A study of Rattus norvegicus with 8 samples.

How the data were processed

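RNA of the renal cortex and of the outer medulla of male Sprague-Dawley rats was measured on Clariom S rat arrays, per the labels, with 1 array for each zone and treatment and 8 arrays in all. The treatments were control, ethylene glycol with alfacalcidol for 2 weeks (EG), phlorizin, and EG with phlorizin. The labels say that kidneys were divided into the zones, so the arrays of a treatment can share animals. Whether RNA of several animals was pooled is not given in the sources used here. The deposited values are log2 expression values made by RMA, per the submitters' processing notes. The version of the RMA software is not given in the sources used here, and the log2 base was inferred from the range of the values, 2.28 to 19.7. No raw intensities were used.

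The deposited table holds 24834 probe sets. Of these, 1646 control and other probe sets were left out, which left 23188 for transcripts. A gene symbol was available for 15049 of them, and 8139 had no gene name in the tables used here. For the 10 symbols with several probe sets, the probe set with the highest mean over the arrays stood for the gene. Probe sets were tested where the highest of the 8 values reached the median of all values (7.54), which left 13163, of which 9315 had a gene name. Values were used as deposited, without further normalization. Signal over background limits the precision of dim genes, since 23 background probes averaged 5.53 to 5.68 per array.

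All tests used limma 3.58.1 in R 4.3.3 with moderated variances, 2-sided p-values and the Benjamini-Hochberg adjustment, at an adjusted p under 0.05. EG and phlorizin were tested together on 4 profiles, each the mean of the cortex and the outer medulla array of a treatment, so that arrays that can share animals were not counted as separate samples. That fit has 1 residual degree of freedom before moderation, and its residual is the interaction of EG with phlorizin. Zones were compared over the 8 arrays with the treatment as a block. With 1 array per group, the 4 comparisons of treatments within zones carry no p-value, and they are given as counts of probe sets at least 1 apart on the log2 scale in each zone and in both zones in the same direction. For the EG effect with minus without phlorizin, genes were chosen on the mean of both EG differences. That mean shares no chance deviation with their difference if both are equally noisy. With 1 array per group this could not be checked. Extra noise without phlorizin would make the chosen EG differences look smaller under phlorizin.

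Groups of genes were fixed as 41 lists, 17 of them markers of cell types. A list is described by the median difference of its tested members and the percentile of that median among 10000 random lists matched on mean expression in 20 bins. Where members are counted as risen or fallen, the limma p-values were adjusted over all tested probe sets or over the list alone, as stated. The comparisons, tests, filters, gene lists and the rule for naming genes were chosen before the data were examined. That rule names Slc5a1, Slc5a2, Slc2a1, Slc2a2, Spp1, Havcr1, Lcn2, Cyp24a1 and Cd44 in every comparison of treatments. It adds the 10 genes with the largest higher and the 10 with the largest lower difference, ranked by the zone with the smaller one, and for each limma effect the 10 largest in each direction past the threshold. It also adds up to 4 members of each list with the largest mean difference, and passes over uncharacterised loci. Genes are given from these sets as space allows. Members named because they passed after adjustment over their list alone were chosen after their values were seen, as were genes of the closing section.

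The scripts were tested on simulated data with 200 changed genes, drawn with the prior variance that limma had fitted, which the simulation therefore assumes to be right. For EG, 0%, 94% and 100% of genes changed by 1, 2 and 4 on the log2 scale were recovered, with 0, 9 and 14 false calls among 13163. The simulated EG change was equal in both phlorizin arms, so these shares do not hold for genes whose EG difference became smaller under phlorizin. For the zones, 0%, 93% and 99.5% were recovered. The variances of the simulation were first drawn from the moderated values, which gave too many false calls, and were then changed to the fitted prior. Alternatives covered the normalization, the filter, the choice of probe set, the variance prior, the unit of the fit and the size thresholds. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the differences, lists and figures.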

Results

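The study asked how phlorizin, an inhibitor of the sodium-glucose cotransporters SGLT1 and SGLT2, relates to the formation of renal stones. Kidneys of male Sprague-Dawley rats, 10 weeks old, were divided into the cortex and the outer medulla, and RNA of each zone was hybridised to Clariom S rat arrays. Calcium oxalate stones are commonly modelled with ethylene glycol, which the liver turns into oxalate, and alfacalcidol, a vitamin D analogue that raises calcium uptake. This combination, given for 2 weeks, is called EG here. The 8 arrays covered 2 zones and 4 treatments, namely control, EG, phlorizin, and EG with phlorizin. There was 1 array per zone and treatment and so no replicate, and comparisons of single arrays carry no p-value. The labels do not say whether an array held RNA of several animals. Values are RMA values, on a log2 scale as judged from their range. Background probes averaged between 5.53 and 5.68 on the 8 arrays, so a gene with a value near 5 was not above background and a difference from such a value is a lower bound. The highest value in the table was 19.7, and differences of genes near it can be compressed. The precision of each value is limited by the number of arrays.

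Median array values lay between 7.39 and 7.58. Across the 13163 tested probe sets, the phlorizin array correlated with the control array at r = 0.990 in the cortex and 0.992 in the outer medulla. The EG array correlated with the control array at 0.915 in the cortex and 0.926 in the outer medulla, and the array of EG with phlorizin at 0.982 and 0.968. The cortex EG array had the lowest spike-in controls of all arrays. Its poly-A spikes averaged 6.42 against 7.67 to 8.23 on the other cortex arrays, and its hybridisation spikes 10.4 against up to 11.3.

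The zones were separated by genes of several nephron segments, while markers of the straight proximal segment are not counted here. Transporters of the convoluted proximal tubule were lower in the outer medulla. Slc22a8, an organic anion transporter, fell by 11.72 on the log2 scale there (SE 0.16, limma adjusted p = 1.09e-06), Slc5a12, a lactate transporter, by 11.08 (SE 0.21), and Slc5a2, which encodes SGLT2, by 10.69 (SE 0.19). Slc12a3, the thiazide-sensitive cotransporter of the distal convoluted tubule, fell by 11.41 (SE 0.19) and Slc34a1, the main phosphate transporter, by 9.84 (SE 0.27). Genes of the medullary segments rose there. Slc5a3, the myo-inositol transporter, was 5.81 higher in the outer medulla (SE 0.25), the urea transporter gene Slc14a1 6.62 (SE 0.42), and Slc12a1, the furosemide-sensitive cotransporter of the thick ascending limb, 4.64 (SE 0.15). All 15 tested markers of the first proximal segments fell in the outer medulla, as did 8 of 9 of the distal convoluted and connecting tubule. Of the thick ascending limb 9 of 11 rose, and of the thin limb 7 of 8. Adjusted over the list alone, these counts were 15, 8, 10 and 7. Over all probe sets, limma called 6780 with an adjusted p under 0.05 between zones within treatments, 4300 higher and 2480 lower in the outer medulla.

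**Figure D1:**
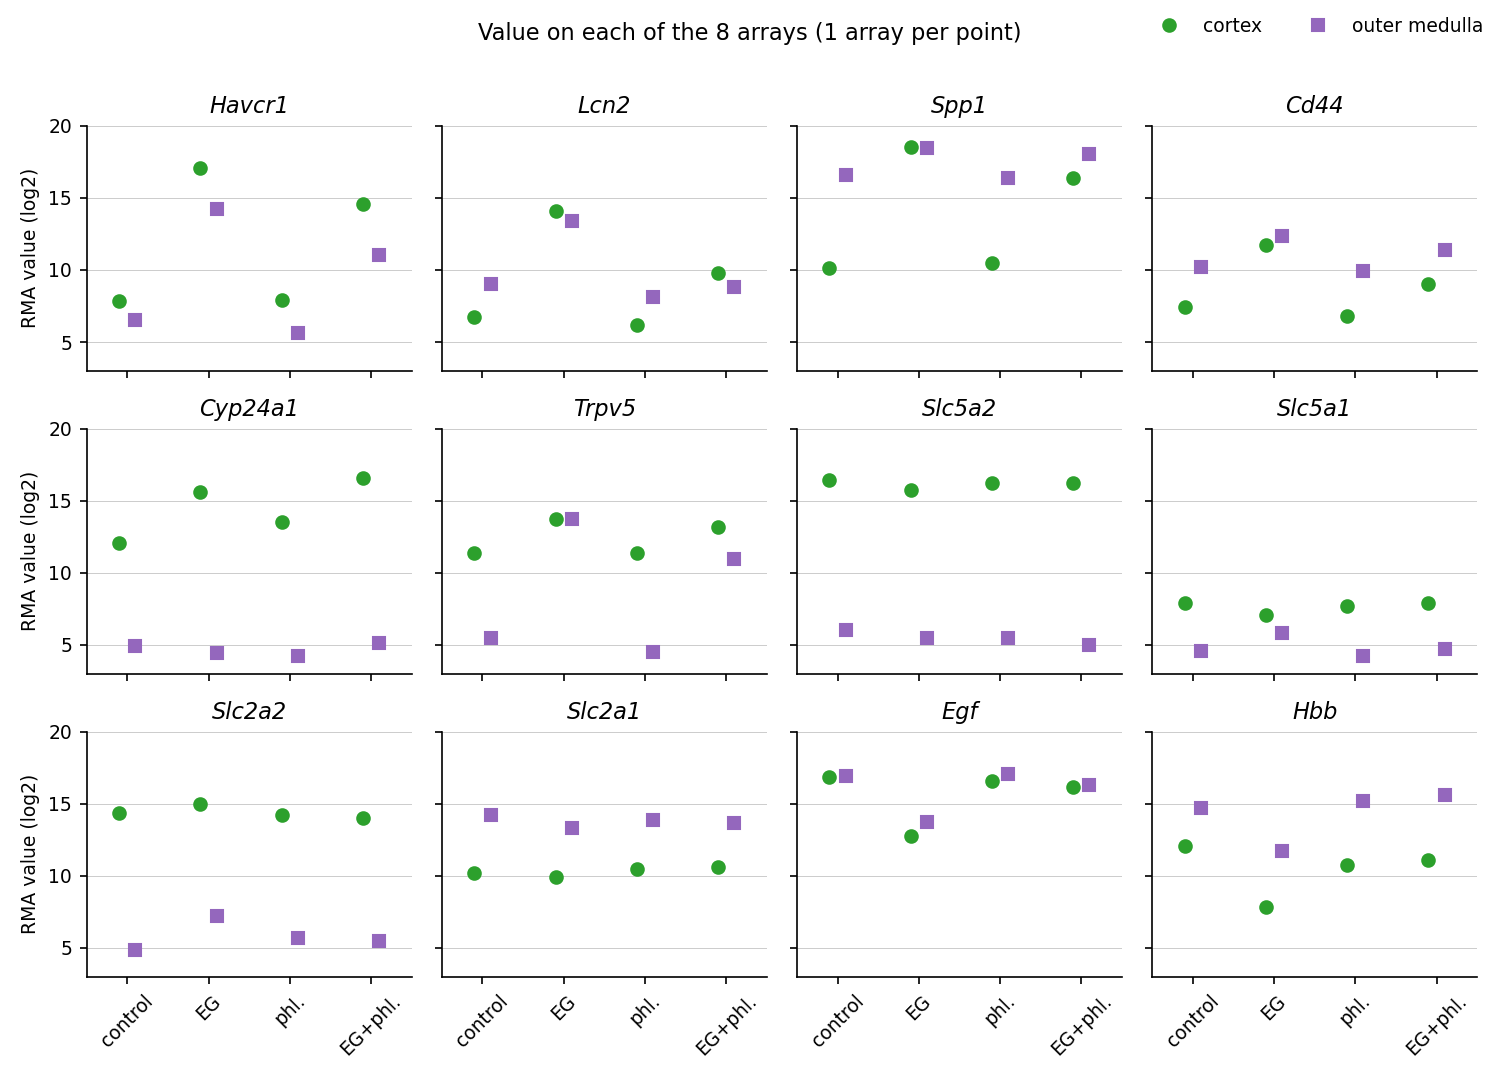
RMA value on the log2 scale of 12 genes on each array, with the treatments on the horizontal axis and 1 point per array (circles, cortex, and squares, outer medulla). Havcr1 stands at 17.05 on the cortex EG array and at 14.61 with EG and phlorizin, against 7.82 in the control, while Slc5a2 stays between 15.73 and 16.46 in the cortex.

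EG was accompanied by a strong tubule injury profile in both zones. Havcr1, which encodes kidney injury molecule KIM-1, went from 7.82 to 17.05 in the cortex and from 6.56 to 14.27 in the outer medulla, differences of 9.23 and 7.71 on the log2 scale. Lcn2, encoding the injury marker NGAL, was 7.35 higher in the cortex and 4.37 higher in the outer medulla. Spp1, which encodes osteopontin, a protein of the stone matrix, went from 10.10 to 18.52 in the cortex, and in the outer medulla, where it was already at 16.57 in the control, to 18.49. Clu, encoding clusterin, was 4.88 and 4.47 higher, and the hyaluronan receptor gene Cd44 4.31 and 2.16. Gpnmb (5.57 and 5.38), Timp1 (4.81 and 4.73) and Slc34a2 (from 7.59 to 14.33 and from 9.04 to 15.05), a phosphate transporter better known from lung and gut, were among the 10 genes with the largest higher values in both zones. Of the 16 tested tubule injury markers 10 were at least 1 higher in both zones and 1 was at least 1 lower. Their median difference was 1.99 in the cortex and 2.05 in the outer medulla, at percentile 100 of random lists for the mean over zones. In the limma fit of EG against no EG over both phlorizin arms, 12 of them rose and 2 fell adjusted over the list alone, and 3 rose adjusted over all genes.

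Matrix, mesenchymal and macrophage genes were higher in EG kidneys as groups. Of 17 tested genes of extracellular matrix and fibrosis, 15 were at least 1 higher in both zones, with medians of 3.11 and 2.83. Col1a1 was 3.78 and 4.24 higher, Col3a1 3.75 and 4.51, Mmp2, a gelatinase, 3.70 and 4.99, and Tnc, encoding tenascin C, 4.70 and 3.47. The crystal matrix and adhesion genes, among them Fn1 (4.46 and 1.98) and the calcification inhibitor Mgp (3.54 and 3.42), had medians of 2.66 and 1.43. Fibroblast markers (2.76 and 2.64) and markers of mesangium, pericytes and smooth muscle (1.36 over both zones) lay higher too. Among macrophage and dendritic cell markers 14 of 18 were at least 1 higher in both zones, with Mrc1 5.10 and 3.36 and Cd68 3.07 and 2.94 higher. Within the fixed list of cytokines and chemokines, C3 (3.02 and 3.29) and Ccl2 (from 8.06 to 11.56 and from 10.85 to 12.31) differed most, and the list's median was 0.82. Cell cycle genes had a median of 1.21 in the cortex and 2.08 in the outer medulla, with the proliferation marker Mki67 going from 8.45 to 10.95 and from 7.62 to 11.84. Each of these lists lay above the 99th percentile of random lists in both zones. In the limma fit, adjusted over the list alone, 16 of 17 matrix and fibrosis genes rose, 10 of 14 crystal matrix genes (with 2 that fell), 7 of 8 fibroblast, 6 of 11 mural, 17 of 18 macrophage, 12 of 17 cell cycle and 5 of 13 cytokine genes. Adjusted over all genes, Spp1 alone of their members rose.

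Genes of intercalated cells, of gluconeogenesis and of the respiratory chain were lower in EG kidneys. The nuclease gene Dnase1 differed by -4.72 in the cortex and -6.31 in the outer medulla, the growth factor gene Egf by -4.11 and -3.25, the potassium channel gene Kcnj10 by -4.06 and -5.20, and the calcium-sensing receptor gene Casr by -3.04 and -3.88. Oxgr1, the receptor for oxoglutarate in the distal nephron, differed by -4.20 and -3.92. Intercalated cell markers had medians of -2.63 and -1.86, with 9 of 14 at least 1 lower in both zones, among them the ammonia transporter gene Rhbg (-3.18 and -2.65) and the proton pump subunit gene Atp6v1b1 (-2.80 and -2.34). The acid-base list (-2.31 and -1.75), which shares 5 genes with it, held Slc38a3, a glutamine transporter, at -4.97 and -1.44. Thick ascending limb markers had medians of -1.52 and -1.39, principal cell markers -0.81 and -0.69, and endothelial markers -0.59 and -0.97. Gluconeogenesis genes (-1.91 and -1.69) included Pck1 (-2.44 and -2.06) and G6pc1 (-2.35 and -3.47), and Ppara, the regulator of fatty acid oxidation, differed by -3.79 and -2.74. The medians of fatty acid oxidation and ketogenesis genes were -0.92 and -1.07, and those of respiratory chain subunits -1.06 and -1.36, both at percentile 0 of random lists for the mean over zones. Red cell transcripts were lower as well, with medians of -2.75 and -2.97 and Hbb at -4.18 and -2.97. In the limma fit, adjusted over the list alone, 10 of 14 intercalated cell genes fell, 7 of 12 acid-base, 7 of 9 gluconeogenesis, 12 of 17 respiratory chain, 4 of 17 fatty acid (with 1 that rose), 4 of 12 principal cell, 2 of 13 endothelial, 1 of 7 red cell and 0 of 11 thick ascending limb genes. That fit counts any inequality of the EG difference between the phlorizin arms as residual. Genes whose EG difference was much smaller under phlorizin can thus hardly pass, and a low count from it does not show that a list was unchanged.

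The 18 tested vitamin D, calcium and phosphate genes had a median of -0.76 in the cortex and 0.09 in the outer medulla, a zone difference that was not tested. Trpv5, the apical calcium channel of the distal tubule, went from 5.48 to 13.76 in the outer medulla and from 11.35 to 13.76 in the cortex. Trpv6 was 5.15 higher in the outer medulla and 1.43 in the cortex. The lower of its control and phlorizin values there, 4.37 and 4.09, lay below background, so neither difference is exact. Cyp24a1, the vitamin D catabolic enzyme, went from 12.05 to 15.64 in the cortex and was near background in the outer medulla (4.91 and 4.44). Of the list of vitamin D, calcium and phosphate genes, 8 of 18 were at least 1 lower and 4 at least 1 higher in the cortex. In the outer medulla 2 were at least 1 lower and 7 at least 1 higher. In the limma fit of EG, 4 of 18 rose and 2 fell adjusted over the list alone, and Trpv5 rose over all genes. The targets of phlorizin differed less. Slc5a2 stood at 16.46 in the control cortex and 15.73 in the EG cortex, and Slc5a1, encoding SGLT1, at 7.90 and 7.10. Slc2a2, the basolateral glucose transporter GLUT2, was 0.62 higher in the cortex and 2.42 in the outer medulla, where the control lay near background at 4.83. Slc2a1, encoding GLUT1, differed by -0.29 and -0.93. Over the 12 glucose transporters the median was -0.61 in the cortex and 0.31 in the outer medulla, and 0 rose and 1 fell adjusted over the list alone. Oxalate handling genes had medians of -1.51 and 0.33, with Grhpr, which reduces glyoxylate, at -2.16 and -1.36, and 1 of 11 fell adjusted over the list alone.

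In all, 1272 probe sets were at least 1 higher and 1671 lower on the cortex EG array than on the control array, and 1130 and 1275 in the outer medulla. Both zones went the same way by that size for 1234, of which 645 were higher and 589 lower. The limma fit compared EG with no EG over 4 profiles, each the mean of both zones, so its residual is the difference between phlorizin arms. It called 5 genes, all of which rose. Gabrp, a GABA receptor subunit, rose by 4.42 (SE 0.26, adjusted p = 0.0214 by limma), Clu by 4.30 (SE 0.26, 0.0214), Trpv5 by 4.74 (SE 0.32, 0.0295), Havcr1 by 7.26 (SE 0.54, 0.0355) and Spp1 by 4.46 (SE 0.36, 0.0463), each higher in both zones and both arms. No gene fell in that fit, while 2992 probe sets of either direction had an unadjusted limma p under 0.05. The count depended on the settings, from 0 with quantile normalization to 1692 with the 8 arrays as samples and the treatment as a random block. With each array centred on its median it was 490 that rose and 396 that fell. The p-values of the fit with 5 calls set the EG difference against its change between the phlorizin arms, technical spread included. As the labels do not state separate animals, they do not measure the spread between animals.

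NADPH oxidase subunits had medians of 1.41 and 1.18 with EG, although in the cortex 3 of 5 were at least 1 higher and 2 at least 1 lower, and 3 of 5 rose adjusted over the list alone. Distal convoluted and connecting tubule markers went opposite ways, with medians of -1.11 in the cortex and 1.63 in the outer medulla. Adjusted over the list alone in the limma fit of EG, 3 of 15 markers of the first proximal segments fell, and of 9 markers of the straight segment 4 fell and 1 rose. For NRF2 and antioxidant genes 2 rose and 2 fell of 18, for ER stress genes 1 and 2 of 13, for interferon genes 3 and 1 of 13, and for distal convoluted and connecting tubule markers 1 and 1 of 9. Of immediate early genes 2 of 11 rose, of thin limb markers 2 of 8, lymphocyte markers 1 of 3 and adipose and adrenal markers 1 of 2. Of the circadian clock 4 of 13 fell, and of podocyte markers 1 of 10. No member passed for glycolysis (17 tested), HIF targets (14), p53 and growth arrest (8), renin-angiotensin (5), osmolyte response (9), cholesterol synthesis (13), neutrophils (2) or urothelium and inner medulla (6).

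**Figure D2:**
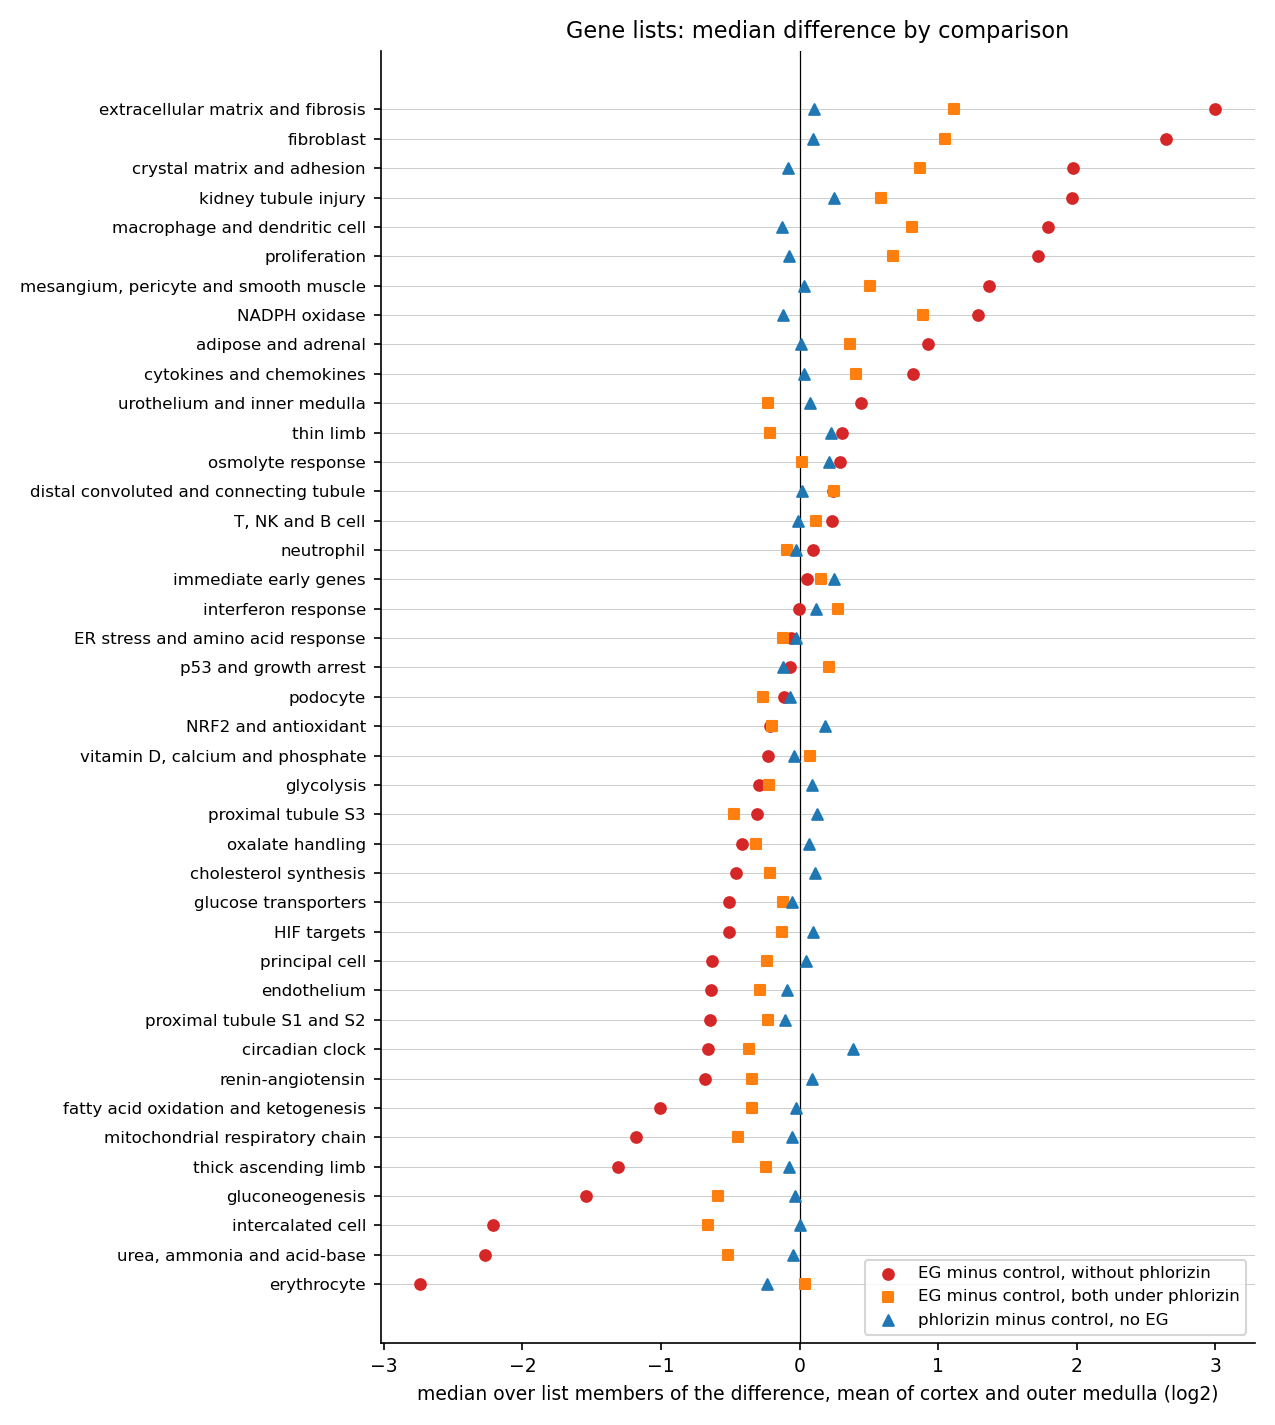
Median log2 difference over the tested members of each of 41 gene lists, averaged over cortex and outer medulla, for EG minus control without phlorizin (circles), EG minus control under phlorizin (squares) and phlorizin minus control without EG (triangles). Fibroblast markers lie at 2.65, 1.05 and 0.10, and red cell transcripts at -2.74, 0.04 and -0.23.

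Under phlorizin, EG was again accompanied by injury, matrix and macrophage genes, by smaller amounts. Havcr1 was 6.69 higher in the cortex and 5.43 in the outer medulla than with phlorizin alone, Clu 3.69 and 4.16, Spp1 5.87 and 1.62, and Slc34a2 3.22 and 4.33. Lcn2 was 3.59 higher in the cortex and 0.65 in the outer medulla, and Cd44 2.18 and 1.40. Among the genes with the largest higher values in both zones were Mmp12, a macrophage elastase (2.46 and 4.39), Serpina3n (2.73 and 3.30), Socs3, a feedback inhibitor of cytokine signals (2.88 and 3.03), Cfi, encoding complement factor I (2.81 and 3.67), and Timp1 (2.22 and 2.56). Among those with the largest lower values were Slc7a12 (-1.39 and -3.43), Slco1a6 (-1.57 and -2.86), Cacng5 (-2.28 and -2.48) and Oxgr1 (-1.72 and -2.13). Tubule injury markers had a median of 0.98 in the cortex and 0.77 in the outer medulla, matrix and fibrosis genes 0.88 and 1.28, and macrophage markers 0.76 and 0.80, each at percentile 100 of random lists for the mean over zones. Intercalated cell markers had medians of -0.46 and -0.90, and red cell transcripts of -0.22 and 0.43. Cyp24a1 was 3.07 higher in the cortex, and Trpv5 1.77 and 6.51 higher. Slc5a2 differed by 0.00 and -0.46, Slc5a1 by 0.21 and 0.51, Slc2a2 by -0.17 and -0.16 and Slc2a1 by 0.15 and -0.23, where Slc5a2, Slc5a1 and Slc2a2 lay near background in the outer medulla. In the cortex 320 probe sets were at least 1 higher and 204 lower, and in the outer medulla 481 and 396. Both zones went the same way for 173, 131 of them higher.

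Among EG animals, those given phlorizin had lower injury and matrix genes and higher thick ascending limb, intercalated cell and red cell genes. Lcn2 differed by -4.35 in the cortex and -4.63 in the outer medulla, Havcr1 by -2.44 and -3.24, Spp1 by -2.15 and -0.46, and Cd44 by -2.71 and -0.99. The complement gene C4b (-3.08 and -2.58), the cytokine gene Il24 (-2.99 and -2.44), the oxidised LDL receptor gene Olr1 (-2.47 and -2.87), Gja1, encoding connexin 43 (-2.65 and -2.50), and A2m (-2.37 and -2.48) were among those with the largest lower values. Dnase1 (4.05 and 3.60), Egf (3.40 and 2.63), Kcnj10 (3.13 and 2.97), Azgp1 (3.57 and 2.17), the anion exchanger gene Slc4a1 (3.76 and 2.27) and Hbb (3.26 and 3.90) were among those with the largest higher values. Medians over lists were -2.36 and -1.33 for matrix and fibrosis, -1.07 and -1.22 for tubule injury, -1.34 and -0.90 for the cell cycle, 1.76 and 1.22 for intercalated cells, 0.93 and 0.83 for the thick ascending limb, and 2.16 and 3.08 for red cell transcripts. For the means over zones, the first 3 lay at percentile 0 of random lists, and the intercalated cell and red cell lists at percentile 100. Cyp24a1 went the other way from the injury genes, with 0.95 higher in the cortex. In the cortex Slc5a2 differed by 0.52, Slc5a1 by 0.81, Slc2a2 by -0.92 and Slc2a1 by 0.69, and Slc2a1 in the outer medulla by 0.33. In the cortex 967 probe sets were at least 1 higher and 814 lower, in the outer medulla 441 and 571, and 377 went the same way in both zones, of which 152 were higher and 225 lower. This comparison shares the EG arrays with the comparison of EG and control, and in simulated unchanged genes such sharing alone gave r = -0.502 between the differences, so the arms were compared without shared arrays.

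The EG differences in the presence and absence of phlorizin, which share no array, correlated across probe sets at r = 0.619 in the cortex and 0.723 in the outer medulla, where genes are not independent replicates. Over the 1380 probe sets whose mean EG difference in the cortex was at least 1 in size, the median size was 2.00 without phlorizin and 0.78 with it. The difference, signed by the direction of EG, had a median of -1.31, and the size was smaller under phlorizin in 96.3% of them. In the outer medulla the 1431 probe sets chosen in the same way had a median size of 1.83 without phlorizin and a median difference of -0.90, and 91.2% were smaller. Of these 1380 and 1431 probe sets, 20 and 15 had the opposite sign under phlorizin. With genes chosen at a mean of at least 0.5 the median differences were -0.80 and -0.53, and with genes chosen in the other zone -0.88 and -0.48. By list, the EG difference with minus without phlorizin was -1.26 in the cortex and -1.63 in the outer medulla for tubule injury, -2.01 and -1.48 for matrix and fibrosis, 2.06 and 0.63 for intercalated cells and 2.53 and 2.91 for red cell transcripts. Cytokines and chemokines, a list that was higher with EG, had 0.00 and -0.04, with list medians without and with phlorizin of 0.73 and 0.73 in the cortex and 0.91 and 0.56 in the outer medulla. Its members did not move alike. With EG, C3 was 8.12 and 9.82 times as high without phlorizin and 1.88 and 2.32 times with it. Ccl2 was 11.3 and 2.76 times as high without it and 6.56 and 1.65 times with it. In 7 of 13 members in the cortex and 6 in the outer medulla the difference lay above 0. These differences come from single arrays and were not tested against replicates.

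**Figure D3:**
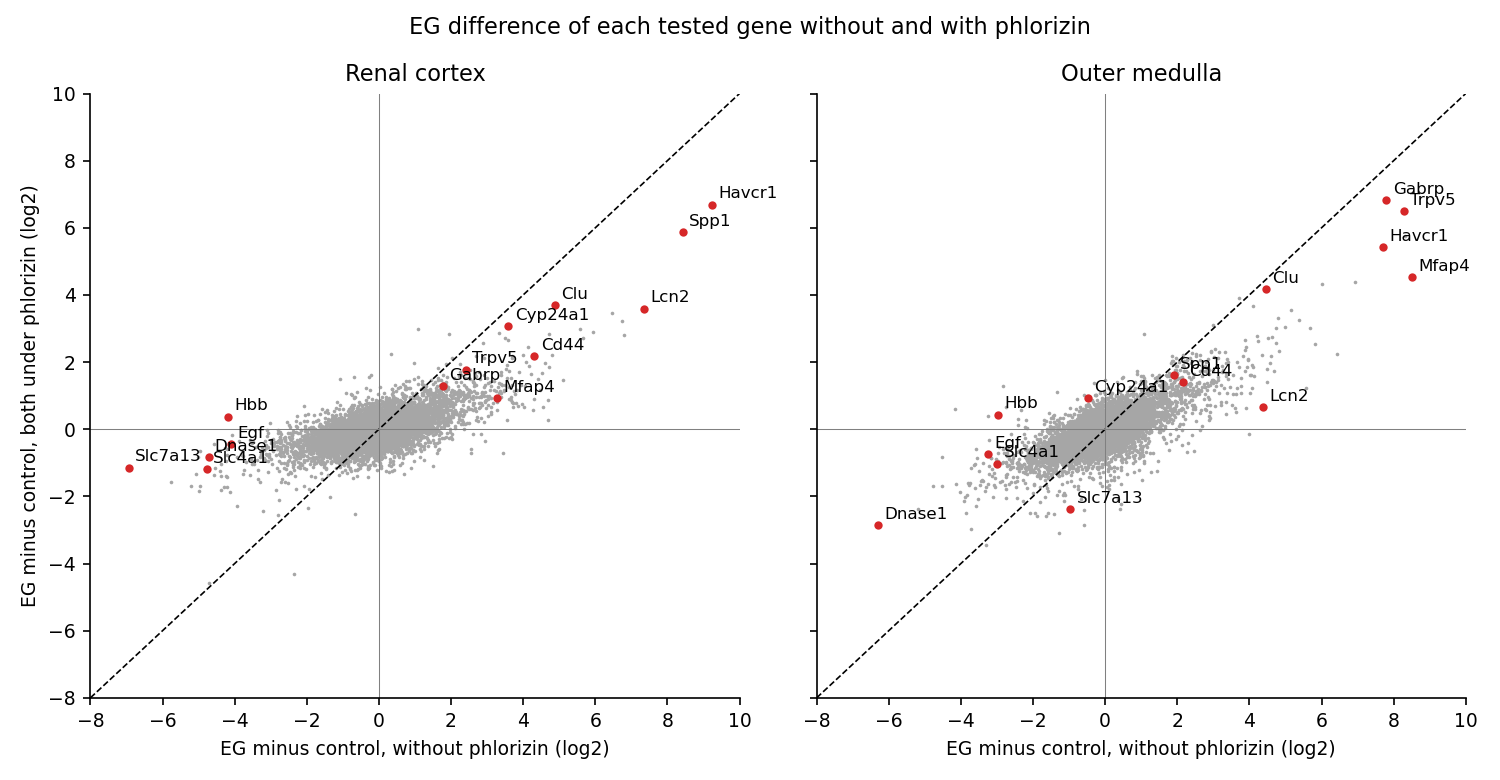
EG minus control on the log2 scale without phlorizin (horizontal axis) and under phlorizin (vertical axis) for each tested gene with a name, in the cortex (left) and the outer medulla (right), with equality as a dashed line and named genes in red. Lcn2 lies at 7.35 and 3.59 in the cortex and at 4.37 and 0.65 in the outer medulla, and Clu in the outer medulla at 4.47 and 4.16.

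Without EG, the phlorizin arrays differed little from the control arrays. The SGLT genes that phlorizin acts on were at like values, with Slc5a2 at 16.46 in the control cortex and 16.25 with phlorizin and Slc5a1 at 7.90 and 7.70. Slc2a2 stood at 14.34 and 14.22 in the cortex, and Slc2a1 at 14.24 and 13.87 in the outer medulla. Havcr1 (0.10 and -0.96), Lcn2 (-0.60 and -0.91), Spp1 (0.40 and -0.17) and Cd44 (-0.57 and -0.23) differed by less than 1 in each zone, and Cyp24a1 was 1.47 higher in the cortex. The genes with the largest higher values in both zones included Cyp2c11, a cytochrome P450 (2.54 and 1.48, near background in the outer medulla), Azgp1 (1.69 and 1.34), the stress-induced factor Atf3 (1.19 and 1.60) and Pdk4, which restrains glucose oxidation (1.01 and 0.96). Those with the largest lower values included Zbtb16, a glucocorticoid-responsive factor (-2.24 and -2.33), Akr1c2 (-3.43 and -1.25), the clock gene Bmal1 (-0.94 and -1.06) and Fos (-0.78 and -1.16). Only 6 probe sets were at least 1 apart in the same direction in both zones, 4 higher and 2 lower, against 86 higher and 66 lower in the cortex and 76 and 27 in the outer medulla. The differences of both zones correlated at r = 0.057 across probe sets. Among lists, the circadian clock had a median of 0.13 in the cortex and 0.63 in the outer medulla, tubule injury markers 0.25 and 0.16, and NRF2 and antioxidant genes 0.26 and -0.04. For the means over zones, these lists had small medians of 0.39, 0.25 and 0.18, at percentiles 100, 100 and 99.99 of random lists. The random lists are matched on mean expression only, so a high percentile can go with a small difference, here and in the other comparisons.

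Over both EG arms, no gene passed an adjusted p of 0.05 for phlorizin in limma, with 468 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.995. The 12 other limma fits that were run gave 0 as well. All of these fits take phlorizin to act alike with and without EG, and count any inequality as residual. A phlorizin difference found only in EG animals could thus hardly pass, and these counts do not speak to it. Adjusted over the list alone, 5 of the 13 clock genes rose with phlorizin, namely the output genes Dbp by 1.03 (SE 0.21), Ciart by 0.93 (SE 0.21) and Tef by 1.01 (SE 0.26), with Per3 by 0.73 (SE 0.21) and Cry2 by 0.73 (SE 0.22). In the same way Cenpf, a cell cycle gene, fell by 1.27 (SE 0.26) and Fst, encoding follistatin, by 0.90 (SE 0.21), while the other 38 lists had no such member.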

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

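The tests of explanations in this part were all chosen only after the results had been seen, as was the inclusion of phlorizin among the differences compared between zones, for which a minimum size set at first was dropped.

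The EG differences were smaller under phlorizin in both zones, among others for injury, matrix, macrophage and intercalated cell genes. Compressed values on the arrays of EG animals given phlorizin are argued against by the spread of their cortex to outer medulla differences, whose SD over probe sets was 0.989 of that of the control arrays. The quality of the cortex EG array, whose spike-in controls were the lowest of all arrays, was not tested as a cause in the cortex. A lower exposure to alfacalcidol stays open, although its target genes Cyp24a1, Trpv5 and Trpv6 kept shares of their EG difference at a median percentile of 85.7 among raised genes. Only Cyp24a1 (91.6) and Trpv5 (85.7) in the cortex started above background. Trpv6 in the cortex (95.6) did not, and Trpv5 (79.2) and Trpv6 (69.1) lay lower in the outer medulla. It also stays open that the animals or pools differed in stone burden whatever their treatment, which cannot be told apart from an action of phlorizin with 1 array per zone and treatment.

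The EG arrays of the zones differed less from each other than the control arrays did, with an SD of zone differences 0.73 of that of the control arrays. On the phlorizin arrays, 570 probe sets were at least 3 higher in the cortex and 333 in the outer medulla. On the cortex EG array these 570 had a median of -1.57 against the control. Mixing of the zones at dissection would need 66.3% of outer medulla tissue for that loss. The 333 outer medulla probe sets lay at a median of -2.80 from the level this share requires. That level came from control arrays, and these probe sets differed by a median of -0.88 on the outer medulla EG array. Outer medulla tissue in the cortex EG sample is argued against as the whole cause of the loss. Cortex tissue in the outer medulla EG sample was not tested. A lower share of proximal tubule cells alone is argued against by the markers of the first proximal segments, which differed by -3.24 to 0.23, with an SD 7.41 times that between the phlorizin and control arrays. Changed expression within the cells of both zones in stone disease stays among the open explanations, as untested, together with mixtures of these causes. Compressed values on the cortex EG array were not tested and stay open too. The interquartile range of that array was 4.66, against 4.85 to 4.99 on the other cortex arrays, and its spike-in controls were the lowest of all arrays.

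Clock genes differed between the phlorizin and control arrays. The median of 8 output genes and repressors less that of 3 activators was 0.58 in the cortex and 1.98 in the outer medulla. Another hour of tissue collection could give opposite moves of these arms, and cannot be told apart from an action of phlorizin, since the hours of collection are not given in the sources used here. The unequal size in zones of the same treatment does not decide it, since the bound of 0.3 set on that inequality was added after these values were seen. In EG animals the arms did not go opposite ways in the cortex with phlorizin, where the activators had a median of 0.497 and the output genes of 0.83, against -0.08 and 0.81 in the outer medulla. Clock genes also had lower medians with EG than in controls, without phlorizin. In the cortex and the outer medulla these were -1.27 and -0.91 for the activators and -0.86 and -0.38 for the output genes.

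For the zone effect, 8 splits of the 8 arrays part the arrays of every treatment as the zones do, which is too few for a share under 0.05. The real split called 6780 probe sets, as many as 1 of these 8 splits, itself, and the highest of the others called 0. The others exchange the zones in some treatments, so zone differences enter their residual. Their low counts are thus built in and say nothing on chance.

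Several gene lists lay on opposite sides of 0 in the zones, in both arms of a contrast, and these differences were not tested. For EG, the cortex median less the outer medulla median, averaged over the arms without and with phlorizin, was -1.63 for the distal convoluted and connecting tubule, 0.68 for immediate early genes, 1.03 for the interferon response, -1.06 for podocyte markers and -0.53 for vitamin D, calcium and phosphate genes. For phlorizin, averaged over the arms without and with EG, it was 0.65 for NRF2 and antioxidant genes, 0.60 for glucose transporters, -0.60 for the interferon response, -0.54 for the osmolyte response, 0.65 for markers of the first proximal segments, 1.16 for the straight segment and 0.56 for vitamin D, calcium and phosphate genes. These are 12 of 82 comparisons of lists between zones, where 10.2 would meet this condition by random signs alone, and some of the medians lie close to 0. Among 136 comparisons of single genes, Fst lay so apart for EG, with an averaged difference of 1.65 between zones, and Pck1 for phlorizin, with 1.08, both untested. For Pck1, 2 of the values lay close to 0, a size of 1.02 times in the cortex without EG and in the outer medulla with EG. Some of the genes compared were named for going the same way in both zones, so a low number is partly built in. No array stood apart from the other 3 of its zone past the limit for 4 samples in 5 measures, with the largest gaps over range 0.695 for the median of the outer medulla EG array and 0.69 for the poly-A spikes of the cortex EG array. This check compared 4 arrays of different treatments at a time, so it can miss an array of poor quality. The poly-A spikes of the cortex EG array averaged 6.42, against 7.46 to 8.23 on all other arrays of both zones.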

How the results depend on the processing

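Leaving out the cortex EG array was chosen only after the data were seen, and the other alternatives were planned. The count of EG genes, 5 as reported, was 0 with quantile normalization and with a filter at the 75th percentile, 886 with arrays centred on their median, 631 without a filter, 59 with a trend in the variance prior and 2 with the robust prior. It was 1103 with 8 arrays as separate samples, 1692 with the treatment as a random block, 7 in the cortex alone, and 355 in the outer medulla alone. Without the cortex EG array it was 275, in a fit with the other 7 arrays as separate samples, so that 2 choices changed and its like is the count of 1103 with 8 arrays. The fits on 7 or 8 arrays count zones that can share animals as separate samples. All 5 genes were among those called with centring, no filter, the trend, both 8-array fits and the outer medulla alone, 3 in the cortex alone and without the cortex EG array, 2 with the robust prior and 0 with quantile normalization or the stricter filter. For phlorizin the count was 0 throughout. The zone effect stayed within 1.5 times its count, between 4596 and 7480. At thresholds of 0.5 and 1.5, EG against control gave 3252 and 535 probe sets in both zones, 6503 and 1411 in the cortex and 5601 and 1162 in the outer medulla. Under phlorizin EG gave 990 and 41, 2694 and 118, and 3574 and 288. Phlorizin in EG animals gave 1676 and 112, 5203 and 698, and 3960 and 309, and in controls 176 and 1, 1807 and 15, and 1310 and 6, since a lower threshold admits more probe sets. With the filter at the 75th percentile, which tests fewer probe sets, EG against control gave 1897 in the cortex, EG under phlorizin 302 and 551, and phlorizin in controls 3 in both zones, 53 in the cortex and 39 in the outer medulla. Without a filter phlorizin in controls gave 384 and 244. Without the cortex EG array only the outer medulla is left, with 2405 for EG against control and 1012 for phlorizin in EG animals. The smaller EG difference under phlorizin kept its sign under every alternative but not its size. In the cortex and the outer medulla it was -0.798 and -0.526 for genes chosen at 0.5, -1.841 and -1.224 for genes chosen at 1.5, and -0.882 and -0.481 for genes chosen in the other zone, and -1.443 in the cortex with the stricter filter. Among list medians, 794 of 816 moved by less than 0.25, and 1 that had stood out from random lists changed sign, the interferon response with phlorizin in controls, at -0.023 under the stricter filter. All 537 values of single genes moved by less than 0.25 or the SD between their zones. The filters do not alter a gene's values, and the choice of probe set alters only those of the 10 symbols with several, so mainly the normalization was tried. For genes whose zones lie far apart that SD is a wide allowance. The neutrophil list had no member left under the stricter filter and gives no value there. For all of these but the thresholds and the number of probe sets tested, the cause was not tested.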

Other observations

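The values of 4 genes of acute-phase or complement proteins are given here for EG, chosen after their values were seen and not as a tested group. Cfi was 6.79 higher in the cortex and 4.11 in the outer medulla, C4b 4.71 and 3.36, A2m 3.38 and 8.31, and Serpina3n 5.66 and 4.80. Under phlorizin the EG differences of C4b were 1.86 and 0.45, and those of A2m 1.36 and 5.74.

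Zbtb16 was lower with phlorizin in control animals and lower with EG, and its values on the control, EG, phlorizin and EG with phlorizin arrays were 8.73, 7.46, 6.49 and 5.99 in the cortex and 11.15, 7.56, 8.82 and 6.54 in the outer medulla. Cyp2c11, higher with phlorizin in controls, differed in the cortex by -2.37 with EG and by -4.31 with EG under phlorizin.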
